A study of Homo sapiens with 36 samples.

How the data were processed

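RNA from LNCaP cells, a line from a human prostate carcinoma that had spread to a lymph node, was measured on Affymetrix HG-U133 A and B arrays. Per the labels, the cells were kept for 3 days in medium with charcoal-stripped serum, which holds little steroid hormone. They were then given ethanol as vehicle (0 nM agonist), the androgen 5α-dihydrotestosterone (DHT) at 10 nM, or RTI-6413-018 at 100 nM, a selective androgen receptor modulator called RTI018 here, for 6 or 24 h. Per the series' design text, the entire experiment was done 3 times, so that each of the 6 groups holds 3 RNA samples and each of the 18 samples was hybridised to both chips (36 arrays). Groups, times and repeat numbers were taken from the sample titles. The description of the chip A array of RTI018 24 h repeat 1 gives 6 h where its title gives 24 h; the title was used.

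The deposited values are signal intensity per probe set on a linear scale, as the authors' value tables hold them. The software that made them and its settings are not given in the sources used here. From the values, each array had been scaled to 1 level: the mean after removing 2% of values at each end lay between 500.1 and 500.2 on all 36 arrays, while the median lay between 144 and 215 on chip A and between 183 and 271 on chip B. The highest intensity was 62335 on chip A and 106865 on chip B. No background estimate or detection call was used, so a low intensity bounds a level poorly, and the number of arrays limits the precision.

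Each value was converted to log2(intensity + 16). Changes are given on this scale, which understates the change of dim probe sets; folds are 2 to the power of the change. Probe sets whose mean log2 value over the 18 arrays of a chip lay above the chip's 40th percentile were kept, which was an intensity of 97.4 on chip A and 142 on chip B. The 68 control probe sets of each chip were left out. This left 13329 of 22215 probe sets on chip A and 13546 of 22577 on chip B. Names came from the platform's annotation: 19065 probe sets of chip A had 1 symbol, 1043 had several and 2107 had none; on chip B these were 15426, 554 and 6597. No gene was named from a probe set with several symbols. Matched against a table of human reference genes, 0 symbols were updated. No genome coordinates were used.

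Each chip was fitted on its own with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with the 6 group means and 1 estimate of spread for all groups. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its chip, and the calls of both chips were added. There were 9 comparisons: each agonist against vehicle and RTI018 against DHT at each time, vehicle at 24 h against 6 h, and for each agonist the difference between its 24 h and 6 h effects. The median residual SD was 0.32 log2 on chip A and 0.44 on chip B. Because the experiment was repeated as a whole, the repeat number pairs the samples by design. On chip A, deviations from the group means correlated between same-numbered samples with r from 0.39 to 0.57 for DHT and vehicle at 6 h, from 0.07 to 0.28 for DHT and vehicle at 24 h, and from -0.38 to 0.19 for RTI018 and DHT at 24 h. The fit with the repeat as a block was an alternative. The p-values measure the spread between these samples.

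For the 28 gene lists, camera of limma with a preset correlation of 0.01 was run on chip A with 1 probe set per gene, the one with the highest mean, and adjusted over the lists of a comparison. The lists held 538 genes, of which 369 were measured on chip A. A gene counts as measured where a kept probe set has its symbol alone. They covered genes known to be induced or repressed by androgen, sterol synthesis, fatty acid synthesis, polyamine metabolism, endoplasmic reticulum folding and secretion, the ATF4 amino acid response, DNA replication, mitosis, cell cycle brakes, immediate early genes, steroid metabolism, receptor coregulators, the TGF-beta and BMP response, glycolysis, mitochondrial respiration, ribosomal proteins, ribosome biogenesis, neuroendocrine genes, interferon response, apoptosis, heat shock, cytoskeleton and adhesion, and luminal identity. Another 4 held markers of fibroblasts, basal epithelium, leukocytes and endothelium. A few genes stand on more than 1 list, among them UGT2B15, UGT2B17, DDC, KLK3 and PMEPA1. Of the 41 list calls in the comparisons of treatments at 1 time, 18 held with an estimated correlation.

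For the lists of induced and repressed genes, the median over genes of RTI018 minus DHT was also taken within each repeat over both chips and tested with an exact two-sided sign-flip test, whose smallest p with 3 repeats is 0.25. The covariance across probe sets of the DHT and RTI018 changes was set beside 100 simulations of unchanged groups against shared vehicle arrays. The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each comparison of treatments, the 8 genes with the largest rise and the 8 with the largest fall among called probe sets that change the same way in all 3 repeats, up to 4 members of each described list with the smallest p, and always KLK3, KLK2, TMPRSS2 and FKBP5. Some items of the rule are not reported here. Other genes were chosen after their values were seen.

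The fit was tested on simulated independent arrays with the spread estimated over all 6 groups of a chip and no effect of the repeat. Changes were added to the DHT 6 h group, which was compared with vehicle at 6 h. Of 50 changed probe sets per size, 0% were called at 0.5 log2, 32% at 1, 98% at 2 and 100% at 3 on chip A, and 0%, 18%, 74% and 96% on chip B. The spread of chip B includes repeat 3, whose vehicle and RTI018 labels are in doubt, so its shares hold only for that spread. Among the calls, 3.36% of 119 on chip A and 3.09% of 97 on chip B were false.

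The alternatives were the repeat as a block, quantile normalization, centring each array on its median, 1 or 64 added before log2, no filter or the 60th percentile, only the compared groups in the fit, eBayes without a trend, array weights, leaving out RTI018 repeat 1, leaving out each sample in turn, the mean of a gene's probe sets in the lists, and camera with an estimated correlation or fry. Chip B without repeat 3, and chip A alone, were added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

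RNA quality was read from the control probe sets. The 3' to 5' ratio of GAPDH was 1.99 on chip A and 2.02 on chip B for RTI018 24 h repeat 2, and at most 1.33 and 1.38 on the other arrays. For beta-actin it was 2.33 and 2.65 in that sample and at most 1.78 and 1.76 elsewhere. No arrays were identical, and the mean r of an array with the other arrays of its group lay between 0.909 and 0.961 on chip A and between 0.830 and 0.911 on chip B.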

Results

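The response of LNCaP cells to a pair of androgen receptor agonists was compared at 6 and 24 h in 18 RNA samples, 3 for each combination of treatment and time, each measured on chips A and B. The series asks how a selective modulator, RTI018, and the canonical agonist DHT differ in the genes they regulate. The doses differed, 10 nM for DHT and 100 nM for RTI018, so that differences between the agonists belong to these doses. Values are intensities with SD and n = 3, and changes are log2 differences with SE from limma.

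The first comparison asks which genes DHT changed within 6 h. KLK2, a secreted kallikrein protease of the prostate, rose from 53.2 ± 34.6 to 6277 ± 1435 (SD, n = 3), a change of 6.60 ± 0.50 (adjusted p = 3.21e-07). FKBP5, a co-chaperone of steroid receptor complexes, rose from 7.13 ± 3.00 to 813 ± 177, by 5.15 ± 0.46 (adjusted p = 1.98e-06). TMPRSS2, a serine protease of the prostate epithelium, rose from 364 ± 30.2 to 3485 ± 706, by 3.19 ± 0.26 (adjusted p = 9.12e-07), and KLK3, which encodes prostate-specific antigen, from 635 ± 280 to 7027 ± 4186, by 3.38 ± 0.62 (adjusted p = 0.00496). These are the probe sets with the largest change, and those of KLK2 ranged from 3.35 to 6.60. The kallikreins KLK2 and KLK3 are close paralogs and may share signal between probe sets, as may ORM1 with its own paralog. Further large rises were those of ORM1, a plasma acute-phase protein, with 3.88, SNAI2, a transcriptional repressor of epithelial genes, with 3.43. CENPN, a centromere protein, stood out too, with 2.94, and OTULINL with 2.89.

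The largest falls with DHT at 6 h were smaller in size. AMIGO2, a cell adhesion protein, fell by 2.01 (adjusted p = 0.000385), MID1, a microtubule-associated ubiquitin ligase, by 1.96, MYRIP by 1.61, the transcription factor MYB by 1.57 and OPRK1, the kappa opioid receptor, by 1.46. IL1RN, which blocks the interleukin 1 receptor, fell by 1.38, BAMBI, a decoy receptor of TGF-beta family ligands, by 1.37, and the collagen chain COL5A2 by 1.34. The probe sets of MID1 ranged from -1.96 to -0.27. Of 30 androgen-induced genes measured on chip A, 22 rose and 0 fell (camera adjusted p = 1.95e-75); adjusted over the list alone, 27 rose and 1 fell. PMEPA1 with 2.70 ± 0.20 and the transcription factor ZBTB16 with 2.28 ± 0.19 were among them. Of 17 genes known as repressed by androgen, OPRK1 fell and LRIG1, an inhibitor of growth factor receptors, rose by 1.76 (camera adjusted p = 0.000643, downward, adjusted p = 0.0697 with an estimated correlation); adjusted over the list alone, 3 fell and 1 rose. In polyamine metabolism 1 of 10 genes rose, ODC1, the first enzyme of the pathway, by 0.89 ± 0.19 (camera adjusted p = 0.0158, adjusted p = 0.173 with an estimated correlation), and 3 adjusted over the list alone. In folding and secretion 1 of 28 rose, the chaperone DNAJB9, by 1.00 ± 0.22 (camera adjusted p = 0.000643, adjusted p = 0.173 with an estimated correlation), and 1 adjusted over the list alone. None of 27 DNA replication genes was called (0 up, 0 down, camera adjusted p = 0.449). In total limma called 198 probe sets, 161 up and 37 down, of which 139 changed at least 2-fold. Without DHT 6 h repeat 1 the count was 120, with only the compared groups in the fit 70, and with array weights 439. The call of MYB was lost without vehicle repeat 1 or 2 or DHT repeat 1 or 3 (highest adjusted p = 0.194), that of ODC1 without vehicle repeat 2 or 3 or DHT repeat 1 or 2 (0.133), and that of DNAJB9 without vehicle repeat 3 or DHT repeat 1 or 2 (0.129).

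RTI018 at 6 h raised androgen-induced genes as well. KLK2 rose by 6.24 ± 0.50 to 5341 ± 3022 (adjusted p = 7.53e-07, n = 3), FKBP5 by 5.25 ± 0.46 to 874 ± 204 (adjusted p = 1.9e-06), TMPRSS2 by 3.02 ± 0.26 to 3081 ± 468 (adjusted p = 1.9e-06) and KLK3 by 3.20 ± 0.62 to 6440 ± 4547 (adjusted p = 0.00771). ORM1 rose by 3.94, SNAI2 by 3.34, OTULINL by 2.97 and ELL2, a transcription elongation factor, by 2.83. AMIGO2 fell by 2.04, the receptor adaptor GRB10 by 2.00, MYB by 1.97, MID1 by 1.95, the membrane protease MMP16 by 1.72, OPRK1 by 1.55, BAMBI by 1.46 and MYRIP by 1.44. Probe sets of 1 gene ranged from 3.04 to 6.24 for KLK2, from 1.497 to 2.97 for OTULINL, from -1.95 to -0.34 for MID1 and from -1.72 to -0.37 for MMP16. Of the 30 androgen-induced genes, 22 rose and 0 fell (camera adjusted p = 1.9e-68), and 28 rose adjusted over the list alone. Of the 17 repressed genes, OPRK1 fell and LRIG1 rose by 2.12 (camera adjusted p = 0.000563, downward, adjusted p = 0.058 with an estimated correlation), and adjusted over the list alone 2 fell and 1 rose. In folding and secretion 1 of 28 rose, DNAJB9, by 0.92 (camera adjusted p = 0.000563, adjusted p = 0.266 with an estimated correlation), and 1 adjusted over the list alone. Polyamine genes were not called (0 of 10, 2 adjusted over the list alone, camera adjusted p = 0.066, and 0.0459 with the repeat as a block). limma called 202 probe sets, 165 up and 37 down, 146 of them by at least 2-fold. The count was 131 without vehicle 6 h repeat 2 and 119 without RTI018 6 h repeat 1, 68 with only the compared groups in the fit, and 362 with array weights. Leaving out 1 sample ended the call of KLK3 (vehicle repeat 2, adjusted p = 0.065; RTI018 repeat 3, 0.0542), of GRB10 (vehicle repeat 2 or 3, RTI018 repeat 1 or 3, up to 0.321), and of MMP16 (vehicle repeat 2 or 3, any RTI018 repeat, up to 0.142), and of DNAJB9 (vehicle repeat 2 or 3, any RTI018 repeat, up to 0.201).

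The agonists were not told apart at 6 h by any single probe set. limma called 0 probe sets between RTI018 and DHT at 6 h, and 0 with the repeat as a block. On chip A 80 of 13329 had an unadjusted p under 0.05, fewer than the share of 0.05 that unchanged probe sets would give on average. Deviations of same-numbered RTI018 and DHT samples correlated there with r from 0.25 to 0.58. The fit without the block counts such shared deviations as spread, which can raise its p-values. The low count is therefore no measure of how alike the agonists are. The difference was -0.17 for KLK3 (95% interval -1.47 to 1.12), -0.35 for KLK2 (-1.40 to 0.69), -0.17 for TMPRSS2 (-0.72 to 0.39) and 0.10 for FKBP5 (-0.87 to 1.06). These intervals, from the fit without the repeat as a block, leave room for differences of 2-fold in either direction for KLK3. In repeats 1, 2 and 3 KLK3 stood at 5858, 3549 and 11673 with DHT, and at 4295, 3363 and 11664 with RTI018. Part of that width is thus spread between repeats that both agonists share. Over the 36 androgen-induced genes on both chips, the median of RTI018 minus DHT was 0.02 ± 0.12 (SD, n = 3 repeats; exact sign-flip p = 0.75), and over the 17 repressed genes -0.03 ± 0.10 (exact sign-flip p = 0.75). None of the gene lists was called between the agonists at 6 h. Of 232 chip A probe sets called at 6 h with either agonist, 212 had a 95% interval of the difference within 1 log2 on both sides of 0.

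**Figure D1:**
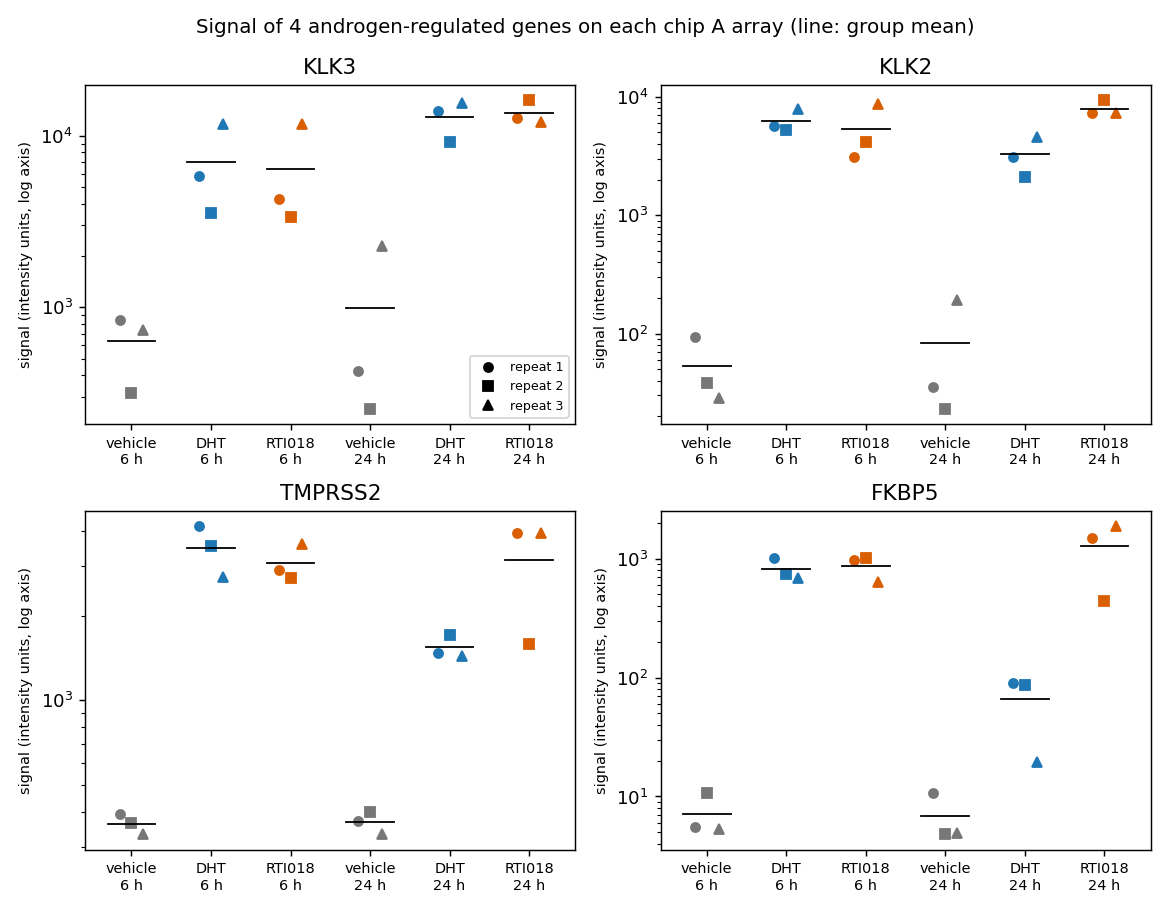
Intensity of KLK3, KLK2, TMPRSS2 and FKBP5 on each chip A array (log axis) in the 6 groups, with a symbol per repeat and a line at the group mean. FKBP5 averaged 813 with DHT and 874 with RTI018 at 6 h, and 65.4 and 1272 at 24 h.

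After 24 h of DHT, genes of DNA synthesis stood beside the androgen-induced genes. KLK2 was raised by 5.38 ± 0.50 (adjusted p = 1.53e-05, n = 3) and KLK3 by 4.29 ± 0.62 to 12959 ± 3321 (adjusted p = 0.000995), while TMPRSS2 was raised by 2.01 ± 0.26 (adjusted p = 0.000588). FKBP5, at 65.4 ± 39.8 against 6.80 ± 3.38 in vehicle, changed by 1.69 ± 0.46 and was not called (adjusted p = 0.0826, 0.0404 with the repeat as a block, 0.0199 without DHT repeat 3). It was called as well with quantile normalization (adjusted p = 0.0437), with array weights (0.00126) and with 1 added before log2 (0.0157), where its change was 2.89. The largest other rises were RRM2, a subunit of ribonucleotide reductase, with 2.79 (1.91 on its other probe set), the cell cycle phosphatase CDC25A with 2.76 and ORM1 with 2.73. With 64 added before log2 the change of ORM1 was 1.46 and not called (adjusted p = 0.0581). They were followed by the replication factors DTL with 2.30 and CDC6 with 2.26, and AZGP1, a secreted glycoprotein, with 2.25. SI, which encodes an intestinal disaccharidase, fell by 2.33, UGT2B15, which conjugates androgens with glucuronic acid, by 2.01, and the cytokine IL1B by 1.90. IGFBP3, a binder of insulin-like growth factors, fell by 1.79, AOC1, a diamine oxidase, by 1.66, the efflux transporter ABCG2 by 1.62, the Ras activator SOS2 by 1.60 and MATN2, a matrix protein, by 1.58. The probe sets of SOS2 were at -1.60 and -0.21, and those of KLK2 ranged from 2.08 to 5.38. UGT2B15 and its paralog UGT2B17 may share signal.

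Among the lists, 12 of 27 DNA replication genes rose with DHT at 24 h and 0 fell (camera adjusted p = 1.47e-27), and 19 rose adjusted over the list alone; MCM2, a helicase subunit, rose by 1.48 ± 0.21. In mitosis 2 of 20 rose, CDK1 by 1.11 ± 0.16 and NUSAP1 by 1.32 ± 0.29 (camera adjusted p = 2.98e-08), and 5 adjusted over the list alone. In fatty acid synthesis 4 of 11 rose, among them the desaturase SCD by 1.43 ± 0.19 and the synthase FASN by 1.30 ± 0.20 (camera adjusted p = 3.37e-09), and 7 adjusted over the list alone. In sterol synthesis 3 of 16 rose, EBP by 0.95, DHCR7 by 1.01 and LSS by 1.09 (camera adjusted p = 4.51e-07), and 7 adjusted over the list alone. Of the 30 androgen-induced genes 9 rose and 0 fell (camera adjusted p = 3.37e-09), and adjusted over the list alone 15 rose and 1 fell. Of the 17 repressed genes 1 fell, UGT2B15, by 1.45 on the probe set used for lists (camera adjusted p = 0.0131, adjusted p = 0.102 with an estimated correlation), and adjusted over the list alone 6 fell and 1 rose. In steroid metabolism 2 of 10 fell, UGT2B15 and AKR1C1, an aldo-keto reductase, by 1.28 ± 0.24 (camera adjusted p = 0.0124), and adjusted over the list alone 5 fell and 1 rose.

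Several further lists shifted with DHT at 24 h without a called member. They were glycolysis (median 0.23 over 19 genes, camera adjusted p = 1.54e-05, 2 up adjusted over the list alone) and ribosome biogenesis (0.42 over 14, adjusted p = 1.09e-05, 0 adjusted over the list alone). Ribosomal proteins had a median of 0.54 over 12 genes (adjusted p = 4.51e-07, adjusted p = 0.168 with an estimated correlation, 3 up adjusted over the list alone). Cell cycle brakes had a median of -0.42 over 14 genes (adjusted p = 0.0131, adjusted p = 0.17 with an estimated correlation, 5 down adjusted over the list alone). Mitochondrial respiration (median 0.14, adjusted p = 0.00667, adjusted p = 0.176 with an estimated correlation), heat shock (0.25, adjusted p = 0.0174, adjusted p = 0.17 with an estimated correlation) and polyamine genes (0.22, adjusted p = 0.0441, adjusted p = 0.17 with an estimated correlation, and 0.0507 with the repeat as a block) were called too, with 0, 0 and 1 member adjusted over the list alone. limma called 185 probe sets with DHT at 24 h, 113 up and 72 down, 128 of them by at least 2-fold, and 458 with the repeat as a block (232 up, 226 down). After centring each array on its median, 141 were up and 51 down. With array weights 2879 were called, 1328 up and 1551 down (789 and 1202 on chip A), so the larger direction turned. The count was 76 without vehicle 24 h repeat 1, 63 without vehicle repeat 2, 86 without DHT repeat 1 and 99 without DHT repeat 2. Leaving out 1 of these 4 samples, or a further 1 of the group, also ended the calls of CDC25A, IL1B, IGFBP3, MATN2, NUSAP1, EBP, DHCR7, LSS, AKR1C1 and, on the probe set used for lists, UGT2B15, with adjusted p up to 0.123, 0.114, 0.0649, 0.145, 0.194, 0.101, 0.103, 0.275, 0.0708 and 0.0809.

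RTI018 at 24 h kept the androgen-induced genes at high levels and lowered many others. KLK2 was raised by 6.73 ± 0.50 to 7968 ± 1194 (adjusted p = 1.26e-07, n = 3), ORM1 by 6.24 ± 0.45 (adjusted p = 1.11e-07), FKBP5 by 5.59 ± 0.46 to 1272 ± 747 (adjusted p = 3.37e-07), KLK3 by 4.38 ± 0.62 to 13589 ± 2205 (adjusted p = 0.000116) and TMPRSS2 by 2.93 ± 0.26 (adjusted p = 1.07e-06). CENPN rose by 4.25, SNAI2 by 3.48, the proteoglycan SPOCK1 by 3.41 and RRM2 by 3.16 (2.28 on its other probe set). COL5A2 fell by 3.92 ± 0.30 (adjusted p = 2.4e-07) and SI changed by -3.82. UGT2B17 changed by -3.69, from 4512 ± 902 to 386 ± 235, UGT2B15 by -3.54 and MID1 by -3.26. PELI2, a ubiquitin ligase of innate immune signalling, changed by -3.11, DDC, the aromatic amino acid decarboxylase, by -3.00, from 12047 ± 1302 to 1538 ± 467, and AMIGO2 by -2.86. The probe sets of MID1 ranged from -3.26 to -0.13 and those of KLK2 from 3.47 to 6.73. The 3' to 5' ratio of GAPDH on chip A was 1.99 in RTI018 24 h repeat 2, against at most 1.33 on the other arrays, and this sample belongs to every value of the group.

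Of the 30 androgen-induced genes, 26 rose with RTI018 at 24 h and 1 fell (camera adjusted p = 6.81e-36); adjusted over the list alone, 27 rose and 1 fell. Of the 17 repressed genes 10 fell and 1 rose (camera adjusted p = 4.87e-08), with DDC, UGT2B15, UGT2B17 and BCHE, a cholinesterase, which fell by 1.66 ± 0.15, among them; adjusted over the list alone 12 fell and 1 rose. In DNA replication 16 of 27 rose and 0 fell (camera adjusted p = 6.05e-19), 19 adjusted over the list alone, with CDC6 by 2.02 and MCM2 by 1.49. In sterol synthesis 8 of 16 rose (camera adjusted p = 4.87e-08), among them DHCR7 by 1.52 ± 0.21 and EBP by 1.24 ± 0.19; adjusted over the list alone 10 rose and 1 fell. In fatty acid synthesis 7 of 11 rose (camera adjusted p = 3.87e-08), among them FASN by 1.41 ± 0.20 and SCD by 1.31 ± 0.19, and 8 adjusted over the list alone. In mitosis 6 of 20 rose, CDK1 by 1.45 among them (camera adjusted p = 8.56e-08, adjusted p = 0.0516 with an estimated correlation), and 9 adjusted over the list alone. In polyamine metabolism 4 of 10 rose, ODC1 by 1.05, SMS by 1.31, SAT1 by 0.87 and SRM by 1.09 (camera adjusted p = 0.00192, adjusted p = 0.0583 with an estimated correlation), and 4 adjusted over the list alone.

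Smaller shifts with RTI018 at 24 h concerned folding and secretion, where 3 of 28 genes rose (camera adjusted p = 0.000353, adjusted p = 0.0764 with an estimated correlation, 3 adjusted over the list alone), and glycolysis, where LDHA, a lactate dehydrogenase subunit, rose by 0.77 (1 of 19, camera adjusted p = 0.00164, adjusted p = 0.0682 with an estimated correlation, 5 adjusted over the list alone). Ribosome biogenesis (median 0.43, adjusted p = 0.00014, adjusted p = 0.0516 with an estimated correlation), mitochondrial respiration (0.17, adjusted p = 0.0339, adjusted p = 0.311 with an estimated correlation) and heat shock (0.25, adjusted p = 0.0207, adjusted p = 0.185 with an estimated correlation) had 0 called members and 0 adjusted over the list alone. Of 4 neuroendocrine genes 3 fell, DDC, the neuropeptide NTS by 1.40 and the enolase ENO2 by 1.04 (camera adjusted p = 0.00822, adjusted p = 0.0759 with an estimated correlation, 3 adjusted over the list alone). Of 5 measured genes on the list of fibroblast markers 3 fell, FN1 by 1.61 ± 0.20, COL3A1 by 1.51 ± 0.29 and COL1A1 by 1.69 ± 0.39 (camera adjusted p = 0.00236, 3 adjusted over the list alone), all matrix proteins that carcinoma cells can make as well. limma called 1223 probe sets, 506 up and 717 down, 645 of them by at least 2-fold. After centring each array on its median there were 729 up and 468 down, since the median change of all chip A probe sets was -0.11 as deposited and 0.03 after centring; rises and falls are relative to it. The count was 762 without vehicle 24 h repeat 1 and 798 without vehicle 24 h repeat 2. Leaving out 1 sample ended the calls of SRM (RTI018 repeat 3, adjusted p = 0.0556), NTS (vehicle repeat 3, 0.0559), ENO2 (vehicle repeat 1 or 3, RTI018 repeat 1 or 2, up to 0.0972) and LDHA (vehicle repeat 1, 0.079; RTI018 repeat 2, 0.0525). Leaving out RTI018 repeat 1 at both times ended that of COL1A1 (adjusted p = 0.0508).

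The direct comparison at 24 h separated the agonists. SNAI2, at 679 ± 165 with RTI018 and 30.7 ± 20.1 with DHT (SD, n = 3), differed by 3.98 ± 0.44 (adjusted p = 4.08e-05), and FKBP5, at 1272 ± 747 and 65.4 ± 39.8, by 3.91 ± 0.46 (adjusted p = 8.91e-05). ORM1 was higher by 3.51, the kinase SGK1 by 3.19, the transcription factor MAF by 2.88, NCAPD3, a condensin subunit, by 2.71, CENPN by 2.69 and OTULINL by 2.54. With RTI018 relative to DHT, COL5A2 fell by 3.10 ± 0.30, DDC by 2.62 ± 0.22, MID1 by 2.52, GRB10 by 2.43, UGT2B17 by 2.42, PKNOX2 by 2.39, the antisense transcript PITX1-AS1 by 2.27 and BARD1, the partner of BRCA1, by 2.22. The probe sets of PKNOX2 disagreed, reaching 1.14 in the other direction, and those of MID1 ranged from -2.52 to -0.04. KLK3 did not separate the agonists, with 0.09 (95% interval -1.21 to 1.39, adjusted p = 0.982), nor did KLK2, with 1.34 (0.30 to 2.39, adjusted p = 0.237), pass the threshold, though it did with only the compared groups in the fit (adjusted p = 0.0481). TMPRSS2 differed by 0.91 (0.36 to 1.47, adjusted p = 0.0901). It was called without RTI018 repeat 2, the sample with the high 3' to 5' ratio (adjusted p = 0.000899).

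Of the 30 androgen-induced genes, 17 were higher with RTI018 than with DHT at 24 h and 1 was lower (camera adjusted p = 4.52e-31); adjusted over the list alone, 23 were higher and 1 lower. NDRG1, which androgen is known to induce, was higher by 1.82 ± 0.21 and PMEPA1 by 1.52 ± 0.20. Of the 17 repressed genes 6 were lower and 1 higher (camera adjusted p = 1.57e-09), and adjusted over the list alone 9 were lower and 1 higher; relative to DHT, OPRK1 fell by 1.57 and BCHE by 1.06. Over both chips the median over 36 induced genes of RTI018 minus DHT was 1.17 ± 0.12 (SD, n = 3 repeats; exact sign-flip p = 0.25, the smallest it can give), and over 17 repressed genes -0.78 ± 0.05 (exact sign-flip p = 0.25). Against vehicle, the induced genes stood at 0.34 ± 0.25 with DHT and 1.84 ± 0.05 with RTI018 at 24 h, and at 1.83 ± 0.27 and 1.82 ± 0.40 at 6 h. These values include repeat 3 of chip B, whose vehicle and RTI018 labels are in doubt, and on chip A alone DHT stood at 0.41 ± 0.09 and RTI018 at 1.89 ± 0.05 at 24 h, with DHT in repeat 3 at 0.42 instead of 0.10. The DNA replication list did not differ (0 of 27 called, 0 adjusted over the list alone, median 0.04, camera adjusted p = 0.752), nor did fatty acid synthesis (0 of 11, camera adjusted p = 0.434, 0 adjusted over the list alone). Sterol synthesis had a median of 0.25 with 0 called members (camera adjusted p = 0.0204, adjusted p = 0.0892 with an estimated correlation, 3 adjusted over the list alone). DNAJB9 alone of 28 folding genes was higher, by 1.08 (camera adjusted p = 0.00926, adjusted p = 0.313 with an estimated correlation, 1 adjusted over the list alone).

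Ribosomal protein genes had a median of -0.35 between the agonists at 24 h with 0 of 12 called (camera adjusted p = 0.0045, adjusted p = 0.601 with an estimated correlation, 0 adjusted over the list alone). Of 4 neuroendocrine genes DDC was lower (camera adjusted p = 0.00482, adjusted p = 0.0998 with an estimated correlation, 2 adjusted over the list alone). Fibroblast markers (2 of 5 lower, FN1 and COL3A1, 2 lower and 1 higher adjusted over the list alone) and cell cycle brakes (0 of 14; 2 higher adjusted over the list alone) were not called (camera adjusted p = 0.0562 and 0.0615), but were with the repeat as a block (adjusted p = 0.0435 for both). ODC1 and SMS were higher by 0.86 and 1.04, while the polyamine list was not called (2 of 10, camera adjusted p = 0.0575, 3 adjusted over the list alone). limma called 285 probe sets between the agonists at 24 h, 147 up and 138 down, 192 of them by at least 2-fold, and 500 with the repeat as a block (253 up, 247 down). After centring each array on its median there were 182 up and 115 down. The count was 182 without DHT 24 h repeat 1, 153 without DHT 24 h repeat 2, and 169 without RTI018 repeat 1, whose array has conflicting times. Leaving out 1 sample ended the calls of GRB10 (DHT repeat 3, adjusted p = 0.0597; RTI018 repeat 3, 0.0505), DNAJB9 (DHT repeat 2, 0.0513; RTI018 repeat 2, 0.0584), COL3A1 (DHT repeat 1 or 2, RTI018 repeat 2 or 3, up to 0.117), ODC1 (DHT repeat 2 or 3, any RTI018 repeat, up to 0.101) and SMS (any DHT repeat, RTI018 repeat 1 or 3, up to 0.123).

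**Figure D2:**
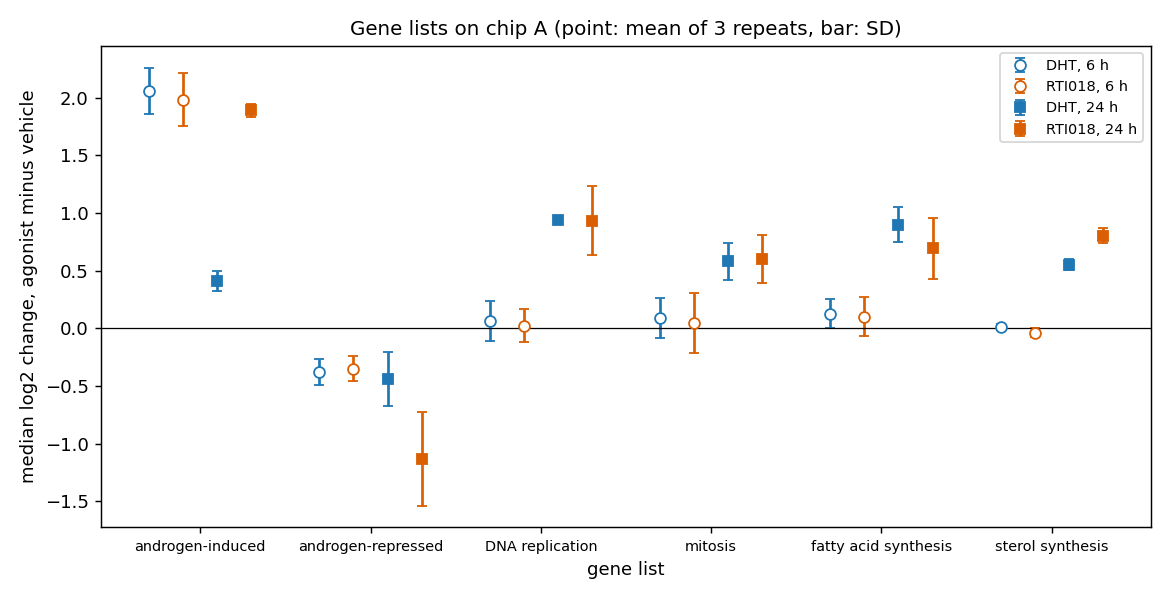
Median log2 change against vehicle over the measured genes of 6 lists on chip A, for DHT and RTI018 at 6 and 24 h, as the mean of the 3 repeats with SD. The androgen-induced list stood at 0.41 with DHT and 1.89 with RTI018 at 24 h, the DNA replication list at 0.94 and 0.93.

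The overlap of calls between the agonists was large at both times. At 6 h, 138 probe sets were up in both lists of 161 and 165, where independent lists would share 1.99, and 30 were down in both lists of 37, against 0.103. At 24 h, 101 of the 113 rises with DHT were also among the 506 with RTI018 (4.29 for independent lists), and 62 of the 72 falls among the 717 (3.87). None was called in opposite directions (0 of either time). Both agonists were compared with the same vehicle arrays, too few to be split with at least 2 arrays on each side, so part of the excess may come from the shared controls. Over both chips the covariance of the changes was 0.0980 at 6 h (r = 0.704), where shared vehicle arrays alone gave 0.0680, and 0.133 at 24 h (r = 0.578), where they gave 0.0679. On chip A it was 0.106 (r = 0.815) at 6 h and 0.156 (r = 0.657) at 24 h, against 0.0478 and 0.0477. The simulated arrays were independent and carried no shared effect of the repeat, so the simulation is not the no-change value of paired samples, and no excess over it is claimed. These correlations run across probe sets, which are not independent replicates. The covariance without 1 sample of both chips reached 0.174 at 6 h (vehicle repeat 2) and 0.253 at 24 h (vehicle repeat 3).

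**Figure D3:**
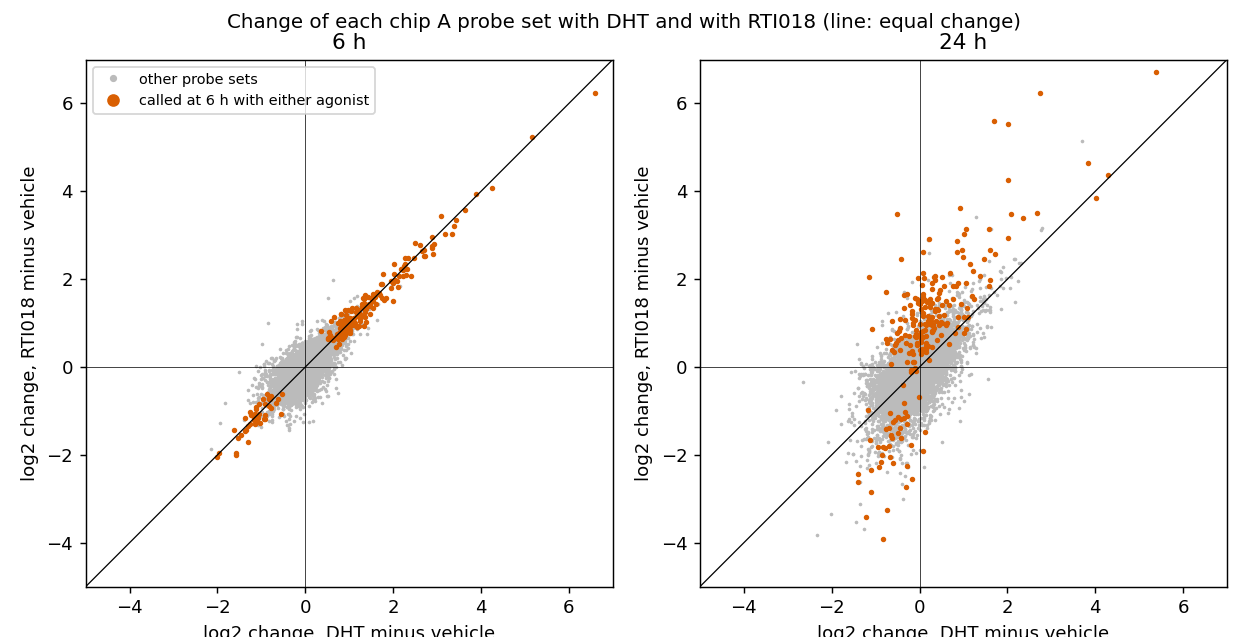
Log2 change of each chip A probe set with DHT (horizontal) and RTI018 (vertical) at 6 and 24 h, with the 232 probe sets called at 6 h with either agonist in colour and a line of equal change. In the direction of their 6 h change these 232 had a median of 1.18 with DHT and 1.17 with RTI018 at 6 h, and of 0.32 and 1.28 at 24 h.

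Whether the effect of an agonist changed between 6 and 24 h was tested as an interaction. With DHT, the difference between the effects at 24 and 6 h was -3.93 ± 0.62 for SNAI2 (adjusted p = 0.00564), -3.81 ± 0.51 for SGK1, -3.46 ± 0.65 for FKBP5 (adjusted p = 0.0185) and -2.80 ± 0.46 for OTULINL. It was 2.67 ± 0.44 for DTL and 2.69 ± 0.53 for RRM2. With RTI018 it was 3.07 for RRM2 and 2.57 for DTL, and -3.33, -2.60 and -1.97 for UGT2B17, DDC and COL5A2 (adjusted p = 0.00323, 0.00111 and 0.00392). limma called 59 probe sets for DHT (11 up, 48 down, 112 with the repeat as a block) and 48 for RTI018 (17 up, 31 down, 107 with the block, 29 up and 24 down after centring). With array weights there were 637 for DHT (278 up, 359 down) and 200 for RTI018 (78 up, 122 down). Without 1 sample of 6 h the count for DHT was 36 (vehicle repeat 3), 28 (DHT repeat 1) or 35 (DHT repeat 2). Without 1 sample of 24 h it was 37 (vehicle 24 h repeat 1), 35 (vehicle 24 h repeat 2), 37 (DHT 24 h repeat 1), 36 (DHT 24 h repeat 2) or 37 (DHT 24 h repeat 3). That for RTI018 was 31 without vehicle 6 h repeat 2 and 30 without RTI018 6 h repeat 3. Between the vehicle groups limma called 0 probe sets at 24 h against 6 h, 0 with the repeat as a block and 1 without vehicle 6 h repeat 2. On chip A 145 of 13329 had an unadjusted p under 0.05 between these groups, again fewer than a share of 0.05. Same-numbered samples of the vehicle groups correlated there with r from 0.24 to 0.51, so this count has the same limit as that between the agonists. KLK3 stood at 635 ± 280 and 987 ± 1125 in these groups.

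Among the lists, the effect of DHT on the 30 androgen-induced genes was smaller at 24 h than at 6 h, with 7 down and 0 up (camera adjusted p = 6.43e-19), and 17 down adjusted over the list alone. DNA replication genes went the other way with both agonists, 3 of 27 up with DHT (camera adjusted p = 7.64e-21) and 3 with RTI018 (camera adjusted p = 1.83e-21), and 15 and 14 adjusted over the list alone. With RTI018 the effect on 4 of 17 androgen-repressed genes was lower at 24 h (camera adjusted p = 2.19e-06), and on 5 adjusted over the list alone. Sterol synthesis gained with DHT (0 of 16 called, camera adjusted p = 4.7e-05) and RTI018 (2 of 16, camera adjusted p = 2.16e-09), with 2 and 9 adjusted over the list alone. Between the vehicle groups, ribosomal protein genes had a median of -0.25 (0 of 12 called, camera adjusted p = 0.00033, adjusted p = 0.878 with an estimated correlation, 0 adjusted over the list alone). Steroid metabolism had a median of 0.25 there (0 of 10 called, camera adjusted p = 0.0402, adjusted p = 0.283 with an estimated correlation, 0 adjusted over the list alone).

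On chip B, with every sample at equal weight and an intensity trend, limma called 0 probe sets in each of the 9 comparisons, with or without the repeat as a block, while between 172 and 1046 had an unadjusted p under 0.05. The lowest of these counts lies below, and the highest above, a share of 0.05 of the 13546 tested. With array weights limma called 888 for DHT at 24 h and 199 for the DHT interaction, and without a trend 1 between the agonists at 24 h. On this chip TMPRSS2 had an intensity of 286, 1331 and 24009 in the arrays labelled vehicle 6 h repeats 1, 2 and 3, and of 18345, 17790 and 472 in those labelled RTI018 6 h. Without repeat 3, a setting chosen after the data were seen, chip B gave 56 calls for DHT and 60 for RTI018 against vehicle at 6 h, 27 and 302 at 24 h, and 129 between the agonists at 24 h. Without repeat 1 or repeat 2 it gave 0 in each comparison.

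**Figure D4:**
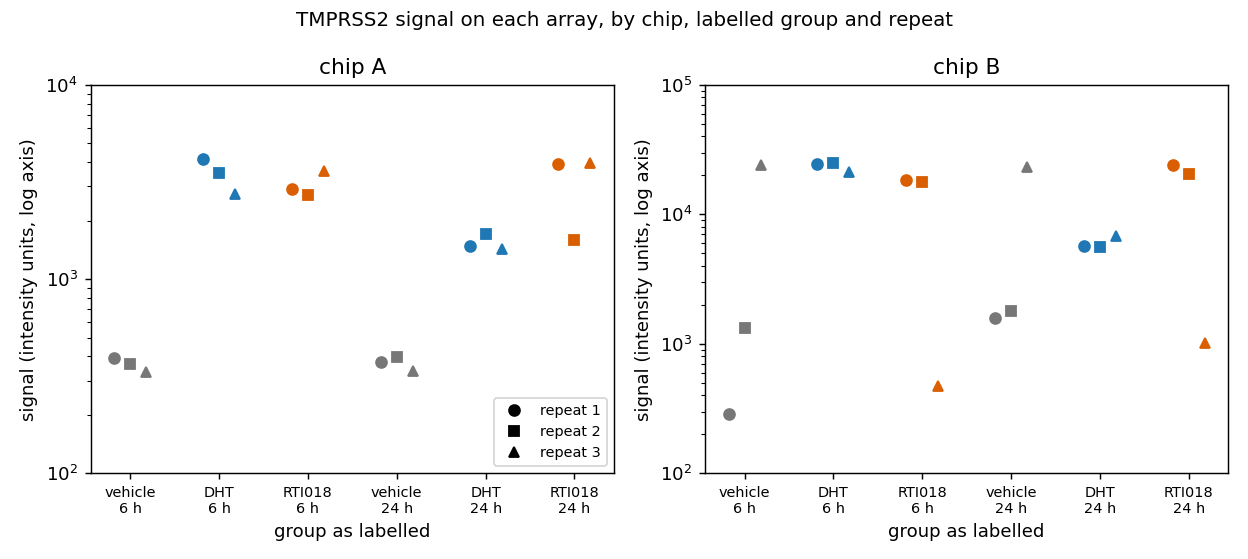
Intensity of TMPRSS2 on each array of chip A and chip B (log axes), by labelled group, with a symbol per repeat. On chip B the array labelled vehicle 6 h repeat 3 had 24009 and the one labelled RTI018 6 h repeat 3 had 472.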

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

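The tests of the explanations below, with their limits, were chosen only after the results were seen, while the interaction tests were planned. The limit for the regrouping of samples was also written afterwards. The effect of an agonist differed between 6 and 24 h, by a test of the difference itself, for 59 probe sets with DHT and 48 with RTI018. With DHT the difference was -3.46 for FKBP5, -3.93 for SNAI2, -2.80 for OTULINL, -3.81 for the kinase SGK1, -2.52 for the transcription factor MAF, -2.28 for the condensin subunit NCAPD3 and -2.28 for IGFBP3. It was 2.69 for RRM2, 2.67 for DTL and 1.97 for CDC6, which act in DNA synthesis. With RTI018 it was 3.07 for RRM2, 2.57 for DTL and 2.19 for CDC6. It was -1.97 for COL5A2, -3.00 for SI, -2.86 for UGT2B15, -3.33 for UGT2B17, -2.60 for DDC and -2.49 for PITX1-AS1.

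Samples were regrouped to see how many calls other groupings give. Of 10 splits of 6 samples, the real one gave 198 calls for DHT at 6 h, 185 for DHT at 24 h and 285 between the agonists at 24 h, against at most 2, 0 and 0 in the others. For RTI018 it gave 202 calls at 6 h and 1223 at 24 h, against at most 118 and 344, all of them on chip B. The 344 came from exchanging vehicle and RTI018 of repeat 3, the exchange weighed below. At 6 h the same exchange, with the 24 h labels left as given, gave 0 calls. The 118 came from another split, which that exchange does not account for. Only 4 of the 10 splits part all pairs of samples with the same repeat number, and among these the highest other count was 0 for RTI018 at 6 h and 344 at 24 h. The number of splits with as many calls as the real one was 1 in these 5 comparisons, and 10 between the agonists at 6 h and between the vehicle groups, where the real count was 0 and the highest other 2 and 15. Such splits are too few for a share under 0.05. Of 100 splits of 12 samples, 2 had at least the 59 calls of the DHT interaction, and 13 at least the 48 of the RTI018 interaction. The highest other counts were 119 and 1073, the latter from exchanging the labels at 1 time, which turns the difference of effects into their sum. Of the 12 other splits with at least 48 calls, 7 keep the 24 h labels whole and still carry the 24 h effect, and those with 179, 92, 127 and 254 calls have them on chip B alone. The last, with 1022 calls, 1012 of them on chip A, mixes the labels at both times. It puts every RTI018 and vehicle array of repeat 3 on the same side of the difference. Differences between repeat 3 and the other repeats may thus enter its count, which was not tested. Counts many times the real one point to a structure of the samples, and chance is not excluded for the RTI018 interaction.

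Chip B gave no call with all 3 repeats at equal weight and an intensity trend, and the arrays labelled vehicle and RTI018 of its repeat 3 were weighed as exchanged. Over genes called on chip A, the median of RTI018 minus vehicle on chip B in repeat 3, signed by chip A, was at most -0.70 at the 2 times, against 0.94 and 1.01 at 6 h in repeats 1 and 2. The correlation of this difference between chips over 100 shared probe sets was at most -0.337 in repeat 3, and -0.178 with control probe sets, measures tried one after another. In repeats 1 and 2 it was 0.0953 and 0.487 at 6 h, and 0.512 and 0.514 at 24 h. With control probe sets it was as low as 0.0758, in repeat 1 at 24 h, so other repeats can lie near 0. A larger spread between all arrays of chip B is argued against by 302 calls without repeat 3 for RTI018 at 24 h. Of the 4 arrays, 4 matched best the chip A array of the exchanged label and 0 that of their own. The matching is imperfect: of 8 vehicle and RTI018 arrays of repeats 1 and 2, 6 matched their own label and 0 the exchanged one. Of 6 DHT arrays, 2 matched their own. Arrays of the same time were set against their shared mean, so their matches are not independent. Exchanging the labels of 1 time alone gave 344 calls on chip B at 24 h and 0 at 6 h. The fit shares 1 estimate of spread over all 6 groups, and the 24 h arrays then kept their labels. The 0 therefore cannot speak against an exchange at 6 h. FKBP5 on chip B had 959, 883 and 24658 in the arrays labelled vehicle 24 h repeats 1, 2 and 3. In those labelled RTI018 24 h it had 27157, 25559 and 939. In repeat 3 at 24 h, TMPRSS2 had 23438 under the vehicle label and 1015.5 under RTI018, and PMEPA1 had 5111 and 629. For these genes the repeat 3 arrays stood nearer the other label than their own. An exchange may explain the missing calls, while no label was changed and no biological explanation was tested.

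Probe sets called at 6 h had a smaller effect of DHT than of RTI018 at 24 h. Selection by their 6 h values is argued against by the androgen-induced list, fixed beforehand, with RTI018 minus DHT at 1.29 on chip A. The array with the high 3' to 5' ratio and the one with conflicting times were weighed by leaving out each repeat alone. Over the 232 probe sets called at 6 h, the RTI018 minus DHT median at 24 h averaged 0.98 with all repeats. Without repeat 2 or without repeat 1 it was at least 0.99, which argues against either array as the whole cause. The DNA replication list stood at 0.94 against vehicle in the DHT 24 h arrays, which shows a response there. That list was picked after its values were seen, so it cannot decide whether these arrays held little treated RNA. In the direct comparison at 24 h, 130 of these 232 probe sets were called between the agonists. Whether the agonist or its dose makes this difference cannot be told apart here and was not tested.

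RTI018 gave more calls than DHT at 24 h, 1223 against 185. RNA quality of RTI018 24 h repeat 2 as the whole cause is argued against by 976 calls without that sample, and scaling of the arrays by 1197 calls after median centring. With array weights chip A kept the order, 2408 calls for RTI018 against 1991 for DHT, while both chips gave 2408 against 2879 through 888 DHT calls on chip B, so the size of the difference depends on the weights. Between the agonists at these doses 285 probe sets were called at 24 h. Agonist and dose cannot be told apart, and the cause of the larger count was not tested.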

How the results depend on the processing

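The settings chip B without repeat 3 and chip A alone were chosen only after the results were seen, the others were planned. No called gene changed direction. The count between the agonists at 6 h was 0 in every setting. The list responses at 6 h stayed within 1 SD of the reported values but crossed 0, from -0.08 to 0.07 for the induced and from -0.08 to 0.02 for the repressed genes. Samples were few, and signal over background was not given, which limits dim genes. The repeat as a block gave 458 calls for DHT at 24 h, 500 between the agonists at 24 h, and 112 and 107 for the DHT and RTI018 interactions. It gave 273 for DHT and 286 for RTI018 at 6 h and 1750 for RTI018 at 24 h, and for the genes named in each comparison and the lists of treatments at 1 time it changed no other call than those named beside the results. With only the compared groups in the fit, which leaves fewer samples for the spread, there were 70 calls for DHT and 68 for RTI018 at 6 h, 777 for RTI018 and 155 between the agonists at 24 h, and 32 and 28 for the interactions. Array weights gave 439 and 2879 calls for DHT at 6 and 24 h, 362 and 2408 for RTI018, 457 between the agonists at 24 h, 1 between the vehicle groups, and 637 and 200 for the interactions. Leaving out RTI018 repeat 1 gave 107 calls for RTI018 at 6 h, 169 between the agonists at 24 h and 25 for the RTI018 interaction. The covariance of the agonists' effects at 6 h, 0.0980, was 0.0716 with 64 added before log2 and 0.141 with chip B without repeat 3, and at 24 h, 0.133, was 0.200 with the latter. The induced list at 24 h, 1.17, was 1.01 with the 60th percentile. The repressed list at 24 h, -0.78, was -0.73 with quantile normalization and with median centring, -0.72 with 64 added, -0.68 without a filter and -1.002 with the 60th percentile. Median centring turned RTI018 at 24 h from 506 up and 717 down to 729 and 468, and its interaction from 17 and 31 to 29 and 24. Array weights kept the order of the agonists at 24 h on chip A (2408 against 1991) and turned it over both chips, through 888 DHT calls on chip B. With an estimated correlation 18 of 41 list calls held. Quantile normalization lost 7, mitochondrial respiration and heat shock with both agonists at 24 h, polyamine and ribosomal proteins with DHT at 24 h, and ribosomal proteins between the agonists. Without a filter 3 were lost, neuroendocrine genes with RTI018 and between the agonists at 24 h and sterol synthesis between them. fry lost 10, folding and polyamine with DHT at 6 h, folding with RTI018 at 6 h, polyamine with DHT, mitochondrial respiration and heat shock with both agonists at 24 h, and folding and ribosomal proteins between them. Only the compared groups in the fit also ended the calls of LRIG1 (adjusted p = 0.0683) and BAMBI (0.053) with DHT at 6 h, and of BAMBI (0.0996), MID1 (0.0582) and MYB (0.0879) with RTI018 at 6 h. The cause was not tested where no construction is named.

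Leaving out 1 sample at a time gave 120 to 173 calls for DHT at 6 h, 63 to 171 at 24 h, 119 to 190 for RTI018 at 6 h, 762 to 1053 at 24 h, 153 to 218 between the agonists at 24 h, 0 to 1 between the vehicle groups, 28 to 59 for the DHT and 30 to 58 for the RTI018 interaction. The covariance ranged from 0.0798 to 0.174 at 6 h and from 0.114 to 0.253 at 24 h.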

Other observations

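The test comparing the androgen-induced and DNA replication lists was chosen only after the result was seen. Several lists had called members without a call of the list. With RTI018 at 24 h, the coregulators GATA2, NCOA1 and NCOA2 fell by 0.81, 1.11 and 1.15 (3 of 11, camera adjusted p = 0.279, 1 up and 5 down adjusted over the list alone), while NCOA2 was not called without vehicle repeat 1 or 2 or RTI018 repeat 2 or 3 (adjusted p up to 0.0967). In apoptosis PMAIP1, a BH3-only protein, rose by 1.29 ± 0.19 (2 of 13 up, camera adjusted p = 0.279, median -0.06, mean 0.06, 2 adjusted over the list alone). TPM1 and VCL, which bind actin, rose by 0.83 and 0.70 (2 of 18 cytoskeleton genes, camera adjusted p = 0.911, 2 adjusted over the list alone). B2M, the light chain of class I molecules, rose by 1.02 against an interferon list median of -0.50 (1 of 13, camera adjusted p = 0.0689, 1 adjusted over the list alone). The cystine transporter SLC7A11 of the ATF4 list fell by 1.24 (1 of 21, camera adjusted p = 0.447, 1 up and 3 down adjusted over the list alone). In the TGF-beta and BMP list 2 of 12 rose and 1, BAMBI, fell by 1.18 (camera adjusted p = 0.580, 2 up and 3 down adjusted over the list alone). Of 10 luminal genes 2 rose, KLK3 and the keratin KRT18 by 0.80, and 2 fell (camera adjusted p = 0.498, 3 and 3 adjusted over the list alone).

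Immediate early genes were not called in any direction with DHT (0 of 13, camera adjusted p = 0.276, 0 adjusted over the list alone) or RTI018 at 24 h (camera adjusted p = 0.770, 0 adjusted over the list alone). Among markers of other cell types, VIM alone of basal epithelium was measured (-0.43 with DHT and -0.51 with RTI018 at 24 h, adjusted p = 0.608 and 0.433) and CD3E alone of leukocytes (-0.11 and -0.04, adjusted p = 0.933 and 0.971). Of endothelium 0 were measured, which can mean an intensity below the filter as well as no probe set.

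The androgen-induced list separated the agonists at 24 h while DNA replication genes rose with both. Over 3 repeats, the RTI018 minus DHT median of the former less that of the latter was 1.26 ± 0.41 (SD, n = 3, exact sign-flip p = 0.25, the smallest possible), a value that decides nothing, since both lists were picked out of 28 for this difference.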
